A study of Mus musculus with 30 samples.

How the data were processed

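Whole mouse lung was profiled on Affymetrix MG-U74 version 2 oligonucleotide arrays, a set of 3 array types (A, B and C) that carry different probe sets. Per the labels, total RNA came from the lungs of animals kept in 10% oxygen in a chamber for 10 h, 2 d, 4 d or 6 d, or from a group titled Norm. The titles do not spell out what Norm stands for. Samples were grouped by their titles, and each group had 2 samples, lettered 1a and 1b, each run on 1 array of each type, which makes 30 arrays. The description attached to the Norm samples speaks of a rejection, a term of transplantation that the titles do not carry. The titles were followed. The labels do not say that 1a and 1b came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

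The deposited values were probe set intensities on a linear scale, 1 per array and probe set, and the software that summarised the probes was not given in the sources used here. The trimmed mean of each of the arrays used, with 2% of the values left out at each end, lay between 800.2 and 800.4, so the deposited intensities were taken as already scaled to a common mean and were used without a further normalization. The rule for this, a spread of the trimmed means of under 5%, was set before the data were examined, as were the tests, the gene lists and the rule for named genes.

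1 array did not enter any test. It is titled Norm 1a on the A type, but its values stand in the table of the B arrays, and its Spearman correlations with the other B arrays lay between -0.00277 and 0.00963. The A arrays therefore held 1 Norm array (1b), and every A comparison against Norm assumes that this array varied as the other groups did. The remaining 29 arrays were used. The Spearman correlation between the 2 arrays of a group lay between 0.872 and 0.971. The number of arrays limits the precision of every value.

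Values below the 40th percentile of all values of an array type (236.05 on A, 297.36 on B and 200.93 on C) were set to that floor, and log2 was taken. Probe sets above the floor on at least 2 arrays were tested, control probe sets left out, which gave 8392 probe sets on A, 8600 on B and 8809 on C, 25801 in all. A group whose arrays all lay at the floor has only an upper bound, and the change is then given as at least that size. For each array type, limma 3.58.1 in R 4.3.3 fitted the 5 group means to all arrays (lmFit, then eBayes with a trend of the variance on the mean level), so that all groups shared one estimate of the spread. The comparisons were each hypoxia time minus Norm, the mean of the 4 hypoxia groups minus Norm, the mean of 4 d and 6 d minus the mean of 10 h and 2 d, and an F test over the 4 comparisons with Norm. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the probe sets of the 3 array types together, with a threshold of 0.05. Changes are log2 differences with the standard error (SE) of the fit, and levels are mean log2 intensities with the SD of the arrays.

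Gene symbols came from the platform annotation supplied with the data, which can be old. On A, 10833 probe sets had 1 symbol, 396 had several and 1193 had none; on B the numbers were 10581, 178 and 1652, and on C 7717, 150 and 4001. No gene was named from a probe set with several symbols. Each of 13039 genes was represented by 1 tested probe set, a plain one before those whose suffix marks probes shared with other transcripts, and among these the one with the highest mean level relative to its array type. The other probe sets of the genes of largest change that passed are given where they went another way. For other genes they mostly are not.

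The text names, for the mean of hypoxia, the 10 genes that rose and the 10 that fell most among those past the threshold; for each other comparison, 5 and 5; for each list spoken of, up to 4 members with the smallest p and any others that passed; and 18 genes chosen in advance for this disease model. Where fewer than 5 genes passed in a comparison, the 10 with the smallest p were named as not passing. A gene named outside this rule is said to have been chosen after its values were seen.

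Of 28 gene lists written in advance, covering pathways and cell types of lung, blood, heart, muscle and fat, 27 had at least 5 tested genes; the list of sex-linked genes had fewer and was not tested. Each list was set against all other genes with limma's cameraPR on the moderated t values, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The test was repeated with a correlation between genes estimated from the residuals of the 9 samples other than Norm 1a (negative estimates set to 0). An estimate under 0.01 made this repeat less strict than the preset test. Members were also counted with p-values adjusted over the list alone. Some genes stand in several lists.

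The procedure was tested on simulated data for 2 d against Norm over 25524 probe sets. Of 100 probe sets changed by 1 on the log2 scale 13% were recovered, and of 100 changed by 2 on that scale 59%, 0 with the wrong sign, while 10 unchanged probe sets were called. Beside the 13 and 59 recovered, these 10 false calls were a larger share than the threshold of 0.05 allows on average. This was a single simulated run. A simulated list of 40 genes shifted by 0.4 was recovered by the list test in the 6 d comparison, and of 100 unshifted lists 2 had an unadjusted p under 0.05. The noise of each simulated probe set was drawn independently. The simulation therefore cannot say how the list test does where genes vary together, as in the cell cycle list (estimated correlation 0.182). The alternatives tried were quantile normalization, median scaling, another floor, a pseudocount in place of the floor, other filters on dim probe sets, eBayes without the trend or with robust estimation, a replicate block, each sample left out in turn, adjustment within an array type, fits to the groups of a comparison alone and genes in place of probe sets. Their effects are given in the closing section.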

Results

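RNA from whole lung was measured on 3 types of oligonucleotide array (A, B and C) in mice kept in 10% oxygen for 10 h, 2 d, 4 d or 6 d and in a group titled Norm, with 2 samples per group. On the A arrays the Norm group held 1 usable array. The series title concerns vascular remodelling after pulmonary hypertension, and the comparisons ask which transcripts of the lung differed from Norm at each time in low oxygen and between early and late times. The values are the deposited array intensities, scaled to a common mean, and changes are log2 differences with the SE of the limma fit. The 4 comparisons with Norm share the same Norm arrays. Probe sets tested numbered 25801, of which 1290 would pass an unadjusted p under 0.05 by chance alone.

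The RNA of the 2 d samples stood apart from that of the other groups on control probe sets. The ratio of 3' to 5' signal of Gapdh, a control of RNA integrity, lay between 3.64 and 4.60 on the 2 d arrays and between 0.786 and 1.68 on all others. For beta-actin the ratio lay between 3.64 and 4.98 at 2 d, between 0.474 and 1.66 at 6 d and between 0.0272 and 0.926 elsewhere. By the order of deposit, the 2 d and 6 d arrays of every type stand in a single run and the Norm, 10 h and 4 d arrays in others. The comparisons of 2 d and 6 d with Norm therefore cross between runs, and there a batch cannot be told apart from the time in low oxygen. The comparisons of 10 h and 4 d with Norm do not mix these runs, and late minus early is balanced over them. The Norm pair itself differed in the beta-actin ratio, at 0.0453 (1a) and 0.775 (1b) on B and 0.104 and 0.926 on C. The 10 h and 4 d arrays of these types lay between 0.0272 and 0.157. Their comparisons with Norm therefore cross a difference in this control, whose cause was not tested. The brightest A signal of an array was 23940 to 45950 at 2 d and 6 d, against 14170 to 23380 in the other groups. On the A arrays, the samples labelled Norm 1b and 4 d 1a correlated better with B and C arrays of the opposite label than of their own, by 0.157 and 0.0747 on B and by 0.116 and 0.0662 on C. With the B and C arrays alone, chosen after seeing the data and with fewer genes per list, 37 of the 40 list calls described here could be tested. Of these 8 were kept, 21 ended and 8 turned in direction, while both inflammation calls and the lymphocyte call had too few genes. Those kept were alveolar type 2 cells at 6 d and from early to late, ciliated cells at 2 d, at 6 d and in the mean, erythroid genes at 2 d, cell division at 6 d and macrophages from early to late. The muscle lists, of which those arrays held 5 skeletal and 12 cardiac genes, were among the calls not kept. The skeletal muscle median turned to 0.0682 at 2 d, 0.00195 at 6 d and 0.178 in the mean, at 10 h it was -8.88e-16 with the test pointing higher, and from early to late the test pointed lower.

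**Figure D1:**
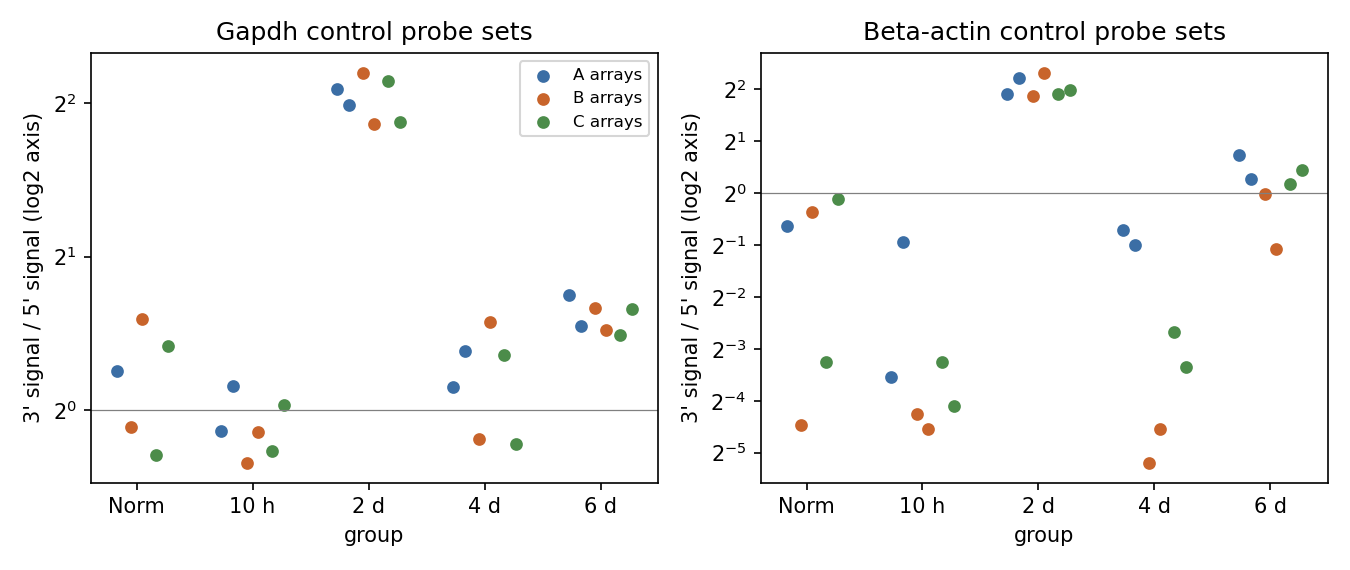
The 3' to 5' signal ratios of the Gapdh and beta-actin control probe sets are plotted for each array by group and array type. The 2 d arrays had Gapdh ratios of 3.64 to 4.60, and the other arrays lay between 0.786 and 1.68.

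After 10 h in low oxygen, genes of stress hormone and interferon responses stood higher in the lung and genes of muscle stood lower. The glucocorticoid-response genes rose as a group (median change 0.38, 18 of 23 genes higher, adjusted p = 2.42e-12), among them Cebpd, a transcription factor (1.46 ± 0.20 SE), the metallothioneins Mt2 (2.13) and Mt1 (1.88), and Fkbp5 (1.26), a co-chaperone of steroid receptors. Interferon-response genes rose with a median of 0.49, 26 of 31 higher (adjusted p = 1.37e-11). Examples were Irf7 at 1.96, Ifit1 at 1.80, Usp18 at 1.54 and Igtp at 0.87. Immediate early genes, the fast transcription factors and their partners, rose with a median of 0.29, 20 of 26 higher (adjusted p = 1.3e-05). Examples were Atf3 at 1.21, Ccn1 at 1.0, Klf4 at 0.64 and Junb at 0.53. Inflammation genes rose by a median of 0.12, 13 of 23 higher (adjusted p = 0.00511, but adjusted p = 0.139 with an estimated correlation). Examples were Ccl2 at 0.86 or more and Cxcl1 at 0.76 or more, with Norm at the floor. Targets of hypoxia-inducible factor were not called at 10 h (median 0.11, 27 of 38 higher, adjusted p = 0.0674), but were with an estimated correlation (adjusted p = 0.0292). For this list that repeat was the less strict test.

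Skeletal muscle genes fell as a group at 10 h, by a median of 0.61 with 15 of 18 lower (adjusted p = 4.06e-14), and cardiac muscle genes fell by a median of 0.38 with 26 of 32 lower (adjusted p = 3.46e-07). Of these, 16 skeletal and 26 cardiac genes were measured on A, where Norm held 1 array. Members with their log2 changes were Atp2a1, a calcium pump of fast muscle (at least -2.19), Tnnc2 (-1.53), Mylpf (at least -1.35) and Myh8 (at least -0.61) of skeletal muscle, and Csrp3 (-1.37), Myl7 (-0.90), Myl4 (-0.83), Myh6 (-0.79) and Tnni3 (-0.77) of heart. Genes of alveolar type 2 cells, which make surfactant, fell by a median of 0.30 with 22 of 28 lower (adjusted p = 0.00211, but adjusted p = 0.160 with an estimated correlation). Among these Egfl6 changed by -0.75, Slc34a2 by -0.70, Chil1 by -0.65 and Sftpb by -0.53. Adjusted over the list alone, 6 glucocorticoid, 4 interferon, 1 immediate early, 2 inflammation, 6 skeletal, 5 cardiac and 0 alveolar type 2 members passed, and over all probe sets 0 did.

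No probe set passed limma's test at 10 h (0 of 25801, smallest adjusted p = 0.0743), and 1577 had an unadjusted p under 0.05. The 10 genes of smallest p, named as not passing, were Acta1, skeletal actin (at least -4.69 ± 0.44 SE, adjusted p = 0.0743), Ppp1ca, a catalytic subunit of protein phosphatase 1 (-1.51, adjusted p = 0.0743), Fst (at least 2.11, Norm at the floor, adjusted p = 0.110), Cebpd (1.46, adjusted p = 0.259), Usp35 (-2.63), Hspa1b (1.85), Pdzd8 (-1.96), Atp2a1 (at least -2.19), Myh1 (at least -1.36, adjusted p = 0.262) and 1700013D24Rik (at least 1.12, adjusted p = 0.282). Edn1, the precursor of the vasoconstrictor endothelin 1, read 9.47 on the Norm array and 11.69 ± 0.05 SD at 10 h (n = 2), a change of 2.21 ± 0.39 SE that did not pass the adjustment (adjusted p = 0.282, other probe set 1.69). Without the Norm 1b arrays, which leaves no A array of Norm, the interferon call ended (adjusted p = 0.0985), and the glucocorticoid, inflammation and skeletal muscle lists had too few genes to be tested. With the B and C arrays alone, which held 14 of its genes and 8 of the glucocorticoid genes, adjusted p was 0.827 and 0.649. The alveolar type 2 call ended without Norm 1a or 10 h 1a (adjusted p up to 0.278) and with quantile normalization (17 of 28 lower, adjusted p = 0.173). The inflammation call ended without 10 h 1b (adjusted p = 0.161) and with 5 arrays required above the floor (adjusted p = 0.158).

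At 2 d the largest number of transcripts differed, with 480 probe sets past the threshold (200 higher and 280 lower). They included the representative probe sets of 202 genes (69 higher and 133 lower), and 355 genes had at least 1 probe set that passed. Elastin (Eln), the stretch protein of arteries and airspaces, rose by 2.16 ± 0.39 SE (4.48-fold, adjusted p = 0.0397), from 12.70 on the Norm array to 14.86 ± 0.27 SD on both 2 d arrays, and its other probe set read 1.98 (adjusted p = 0.191). The other large rises were Mex3a, an RNA-binding protein (2.40 ± 0.38 SE, adjusted p = 0.0235), Rbks, ribokinase (2.37 ± 0.47 SE, adjusted p = 0.0434), Zfp707 (2.10 ± 0.30 SE, adjusted p = 0.0203) and Snrp1c-ps2 (2.49 ± 0.42 SE, adjusted p = 0.0321), whose probe set reads near copies. The largest falls were Spag6l, a protein of motile cilia (at least -2.91 ± 0.42 SE, adjusted p = 0.0203, other probe set -1.17), Acta1 (-2.72 ± 0.44 SE, adjusted p = 0.0298), Kmt2e (-2.57 ± 0.24 SE, adjusted p = 0.00675), Srrm2, a splicing factor (-2.52 ± 0.21 SE, adjusted p = 0.00432), and Car3, a carbonic anhydrase of muscle and fat (-2.45 ± 0.27 SE, adjusted p = 0.0167). In each of these 10 genes both 2 d arrays lay on the same side of the Norm arrays. Since the genes were picked for large changes between these same arrays, this adds no support. Eln, Snrp1c-ps2, Acta1 and Car3 had only 1 Norm array.

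Muscle and ciliated cell genes fell together at 2 d, in samples whose Gapdh 3' to 5' ratio averaged 4.12 on A, 4.12 on B and 4.06 on C, against 1.19, 1.22 and 1.07 in Norm. Cardiac genes had a median of -0.54 with 27 of 32 lower (adjusted p = 4.56e-07), 4 passed (Csrp3 at least -1.42, Myl4 -1.38, Myl7 -1.33 and Tnni3 -1.03) and 10 passed adjusted over the list alone. Skeletal muscle genes had a median of -0.67 with 13 of 18 lower (adjusted p = 0.00447), 2 passed (Acta1 and Myh1, at -1.28) and 6 adjusted over the list alone. Genes of ciliated cells had a median of -0.38 with 19 of 24 lower (adjusted p = 4.28e-04), 3 passed (Spag6l, Ak7 -1.57 and Sec14l3 -1.0) and 7 adjusted over the list alone. Clock genes had a median of -0.33 with 15 of 20 lower (adjusted p = 0.0164), 1 passed (Nr1d2, a repressor of the clock, -1.66) and 8 adjusted over the list alone, among them Cry1 at 0.84.

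Red cell, growth and matrix genes stood higher at 2 d, in the same samples with raised control ratios. Erythroid genes rose by a median of 0.30 with 26 of 34 higher (adjusted p = 0.0258). Examples were Slc4a1, the anion exchanger of red cells, at 1.92, Hba-a1, an alpha globin, at 1.40, Bpgm at 1.15 and Rhag at 0.79 or more. Cell cycle genes rose by a median of 0.33 with 44 of 53 higher (adjusted p = 0.00254, but adjusted p = 0.560 with an estimated correlation). Examples were Lig1 at 1.48 or more, Mcm3 at 1.10, Ccne2 at 0.78 and Tk1 at 0.76. Matrix genes rose by a median of 0.32 with 40 of 56 higher (adjusted p = 0.0240, but adjusted p = 0.756 with an estimated correlation). Of these 2 passed, Eln and, downward, Timp2, an inhibitor of matrix proteases (-2.37, adjusted p = 0.00518, while a further Timp2 probe set passed at 0.81). Interferon genes fell by a median of 0.18 with 20 of 31 lower (adjusted p = 0.0464, but adjusted p = 0.263 with an estimated correlation). Examples were Oasl2 at -1.84, Iigp1 at -0.85 and Ddx58 at -0.64. Adjusted over the list alone, 0 erythroid, 0 cell cycle, 5 matrix (4 of them higher, Mfap4 2.90, Col4a1 1.20 and Timp1 1.10 besides Eln) and 3 interferon members passed.

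The limma fit gave 4864 probe sets with an unadjusted p under 0.05 at 2 d. Fits to the 2 d and Norm arrays alone ended the calls of all 10 genes above (adjusted p 0.188 to 0.233). Leaving out 1 sample gave counts of 406 and 323 (Norm 1a and 1b), 23 and 21 (10 h), 138 and 106 (2 d), 295 and 246 (4 d) and 15 and 13 (6 d). Srrm2 passed in all 10 of these fits, and Kmt2e lost its call without either 10 h sample (adjusted p up to 0.0538) and Car3 without any 10 h or 6 d sample (adjusted p up to 0.0545). Zfp707, Acta1, Mex3a and Spag6l lost theirs without any 10 h, 2 d or 6 d sample, Mex3a also without Norm 1a and Spag6l without Norm 1b (adjusted p up to 0.135). Eln, Snrp1c-ps2 and Rbks lost theirs without any 1 of the 8 hypoxia samples (adjusted p up to 0.167 for Eln), and Rbks also without Norm 1a or 1b. Eln, Snrp1c-ps2, Acta1 and Car3, measured on A, and the skeletal muscle list could not be tested without Norm 1b. Eln also lost its call with median scaling (adjusted p = 0.0560), no filter on dim probe sets (0.135), no trend (0.0504), the replicate block (0.0731) and adjustment within an array type (0.0771). With no filter Rbks, Snrp1c-ps2, Zfp707 and Acta1 lost theirs (adjusted p up to 0.119). Rbks (0.0650) and Snrp1c-ps2 (0.0551) did with the replicate block, Rbks with the lower floor (0.0706), and Snrp1c-ps2 (0.0574) and Acta1 (0.0551) with adjustment within an array type. Other probe sets of Srrm2 read 0.23, 0.04 and 0.21, and those of Kmt2e -0.36, -0.73 and -1.11. Those of Mex3a, Rbks and Zfp707 read 0.11, 0.27 and -0.34. Without Norm 1b or 2 d 1b the cell cycle call ended (adjusted p up to 0.480), and without these or 2 d 1a the clock (up to 0.112), erythroid (up to 0.163), matrix (up to 0.268) and interferon (up to 0.135) calls. The matrix and interferon calls also ended without 10 h 1a or 1b, and the interferon call without 6 d 1a or 1b. The matrix call ended with median scaling (adjusted p = 0.0541) and the replicate block (0.0548), the erythroid call with the lower floor (0.0534) and the interferon call with no trend (0.0710).

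**Figure D2:**
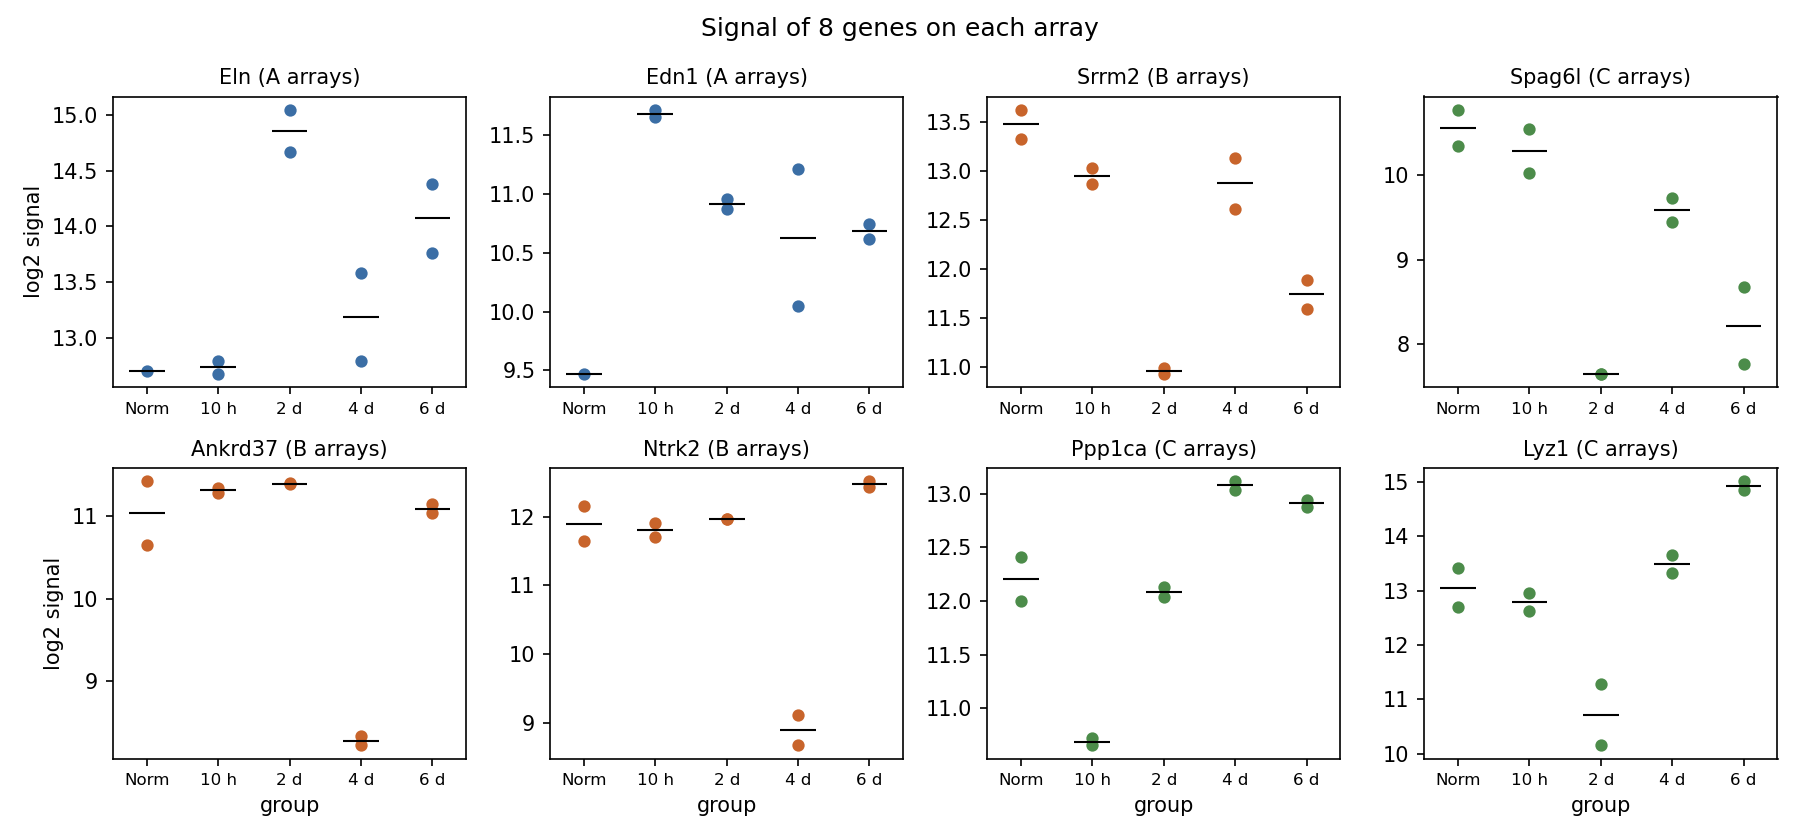
Log2 signal of 8 genes is plotted for each array by group, with a bar at the group mean. Eln averaged 14.86 at 2 d against 12.70 on its Norm array, and Ankrd37 averaged 8.28 at 4 d against 11.04 in Norm.

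At 4 d a pair of genes fell, and cell division genes stood higher as a group. Ntrk2, a receptor of neurotrophins, fell by 3.01 ± 0.20 SE (8.05-fold lower, adjusted p = 0.00281), from 11.90 ± 0.37 SD in Norm to 8.89 ± 0.31 SD (n = 2 each). Ankrd37, known as a gene induced through hypoxia-inducible factor, fell by 2.77 ± 0.22 SE (6.80-fold lower, adjusted p = 0.00682), from 11.04 ± 0.55 SD to 8.28 ± 0.08 SD. Cell cycle genes rose by a median of 0.47 with 43 of 53 higher (adjusted p = 1.14e-07, but adjusted p = 0.194 with an estimated correlation). Examples were Mcm3 at 1.20, Smc2 at 1.12 or more, Kif20a at 1.11 or more and Ccnb2 at 0.90. Over all probe sets 0 of them passed, and 0 adjusted over the list alone. Genes of ciliated cells (19 of 24 lower, adjusted p = 0.0521) and immediate early genes (19 of 26 lower, adjusted p = 0.0736) were not called, but were with an estimated correlation (adjusted p = 0.0420 each). For both lists that repeat was the less strict test.

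Those 2 probe sets, both on the B arrays, were the ones that passed limma's test at 4 d, and 1582 had an unadjusted p under 0.05. Other genes of smallest p did not pass: AU040972 (-1.59, adjusted p = 0.0976), Actb (-2.11, adjusted p = 0.174), Mgst3 (-1.67), Slc16a9 (1.49), Cspg4 (-1.60), Capn1 (-1.94), Ppm1l (1.16) and Fcrla (at least 0.67). Other probe sets of Ntrk2 read -0.06, -0.34 and -1.05. Ntrk2 lost its call without either 2 d sample (adjusted p up to 0.225), and Ankrd37 without any 1 of the 8 hypoxia samples (adjusted p up to 0.274). Fits to the 4 d and Norm arrays alone ended both calls (adjusted p = 0.928 for each). The cell cycle call ended without Norm 1b, where the median turned to -0.30, or without 4 d 1a (adjusted p up to 0.172), and with the B and C arrays alone the median was -0.0138.

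By 6 d genes of cell division, alveolar type 2 cells and macrophages were higher in the lung, and genes of muscle, cilia and the clock were lower. This comparison crosses runs of deposit. The mean Gapdh 3' to 5' ratio at 6 d was 1.57 on A, 1.51 on B and 1.49 on C, against 1.19, 1.22 and 1.07 in Norm. Cell cycle genes rose by a median of 0.60 with 52 of 53 higher (adjusted p = 4.71e-12). Examples were Kif22 at 1.88, Lig1, a DNA ligase, at 1.59 or more, Smc2 at 1.04 or more and Ccnb2 at 0.97. Alveolar type 2 genes rose by a median of 0.38 with 22 of 28 higher (adjusted p = 5.51e-05). Examples were Lyz1, a lysozyme, at 1.87 on a probe set shared with near copies, Egfl6 at 1.03, Etv5 at 0.75 and Il33 at 0.53. Macrophage genes rose by a median of 0.14 with 23 of 33 higher (adjusted p = 0.0215). Examples were Siglecf at 1.39, Ctsk at 0.98 and Chil3 at 0.62 besides Lyz1, which stands in both lists. Matrix genes rose by a median of 0.27 with 41 of 56 higher (adjusted p = 0.00142, but adjusted p = 0.262 with an estimated correlation). Examples were Mfap4 at 3.10 on a probe set shared with near copies and Eln at 1.38.

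Cardiac genes fell at 6 d by a median of 0.36 with 30 of 32 lower (adjusted p = 5.17e-08). Examples were Csrp3 at -1.16, Myl4 at -1.12, Myl7 at -1.11 and Myh6 at -0.75. Skeletal muscle genes fell by a median of 0.51 with 13 of 18 lower (adjusted p = 2.67e-05). Examples were Acta1 at -2.56, Atp2a1 at -1.55, Myh1 at -1.34 and Eno3 at -1.06. Genes of ciliated cells fell by a median of 0.23 with 17 of 24 lower (adjusted p = 8.11e-05). Examples were Spag6l at -2.33, Pifo at -1.33, Ak7 at -1.26, Sntn at -1.23 and Capsl at -0.63. Clock genes fell by a median of 0.37 with 13 of 20 lower (adjusted p = 0.00408). Examples were Usp2 at -1.72, Hlf at -1.04 and Nfil3 at least -0.92. Lymphocyte genes fell by a median of 0.15 with 18 of 29 lower (adjusted p = 0.0271, but adjusted p = 0.185 with an estimated correlation). Examples were Cd79a at -1.09, Ighm at -1.07, Cd52 at -0.95 and, higher, Zap70 at 1.52. Immediate early genes were not called (18 of 26 lower, adjusted p = 0.0600), but were with an estimated correlation (adjusted p = 0.0401). There too the repeat was the less strict test. Adjusted over the list alone, 0 cell cycle, 1 alveolar type 2, 1 macrophage, 1 matrix, 4 cardiac, 5 skeletal, 5 ciliated, 3 clock and 1 lymphocyte members passed, and over all probe sets 0 did.

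No probe set passed limma's test at 6 d (0 of 25801, smallest adjusted p = 0.125), and 2365 had an unadjusted p under 0.05. The 10 genes of smallest p, named as not passing, were Srrm2 (-1.74, adjusted p = 0.125), Nat14 (1.99, adjusted p = 0.150), AU040972 (-1.22), Rai14 (0.81), Kmt2e (-1.55), Ccdc153 (-1.05), Nrep (1.03), Drc3 (-1.12, adjusted p = 0.163), Fam183b (-1.46) and Ppp1r12a (-1.02, adjusted p = 0.189). Without Norm 1b, whose A array was the only Norm array of that type, the cell cycle, clock and matrix calls ended (adjusted p = 0.512), as did the macrophage call (median -0.252), which also ended without 6 d 1a (adjusted p up to 0.155). The lymphocyte call ended without Norm 1a, 10 h 1a, 10 h 1b or 6 d 1a (adjusted p up to 0.153) and with the replicate block (0.133), and neither it nor the skeletal muscle call could be tested without Norm 1b. With median scaling the macrophage (19 of 33 higher, adjusted p = 0.187) and matrix (0.0540) calls ended.

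**Figure D3:**
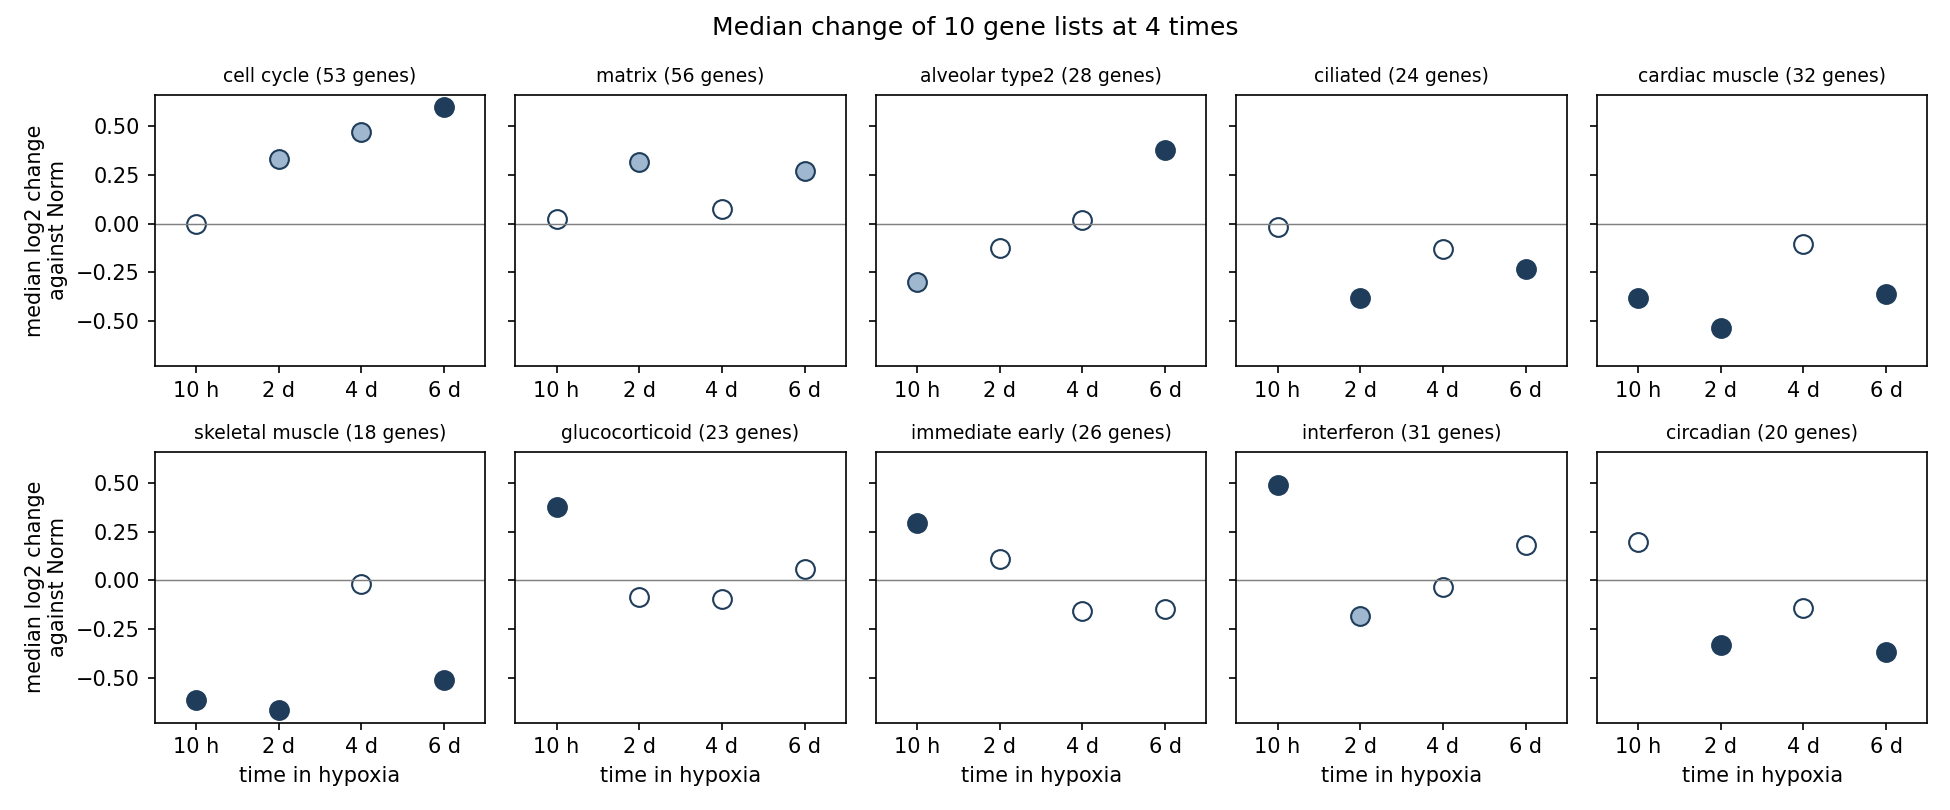
The median log2 change from Norm is plotted for 10 gene lists at 10 h, 2 d, 4 d and 6 d. Dark points mark lists called also with an estimated correlation, light points those called with the preset one alone and open points those not called, and the cell cycle median was 0.33 at 2 d, 0.47 at 4 d and 0.60 at 6 d.

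Averaged over the 4 hypoxia groups, muscle and ciliated cell genes were lower than in Norm and cell division genes higher. Cardiac genes fell by a median of 0.34 with 25 of 32 lower (adjusted p = 1.04e-07), skeletal muscle genes by 0.60 with 12 of 18 lower (adjusted p = 1.64e-06), and ciliated cell genes by 0.21 with 18 of 24 lower (adjusted p = 1.38e-04). Examples were Spag6l at least -1.62 and Ak7 at -0.94. Of the muscle genes, 16 of 18 skeletal and 26 of 32 cardiac ones were measured on A, against a single Norm array. High muscle signal in that 1 sample would by itself lower them at every time, which cannot be told apart from low oxygen. Cell cycle genes rose by a median of 0.35 with 47 of 53 higher (adjusted p = 5.42e-07, but adjusted p = 0.163 with an estimated correlation). Matrix genes rose by a median of 0.14 with 38 of 56 higher (adjusted p = 0.0283, but adjusted p = 0.753 with an estimated correlation). Adjusted over the list alone, 5 cardiac, 4 skeletal, 5 ciliated, 0 cell cycle and 1 matrix members passed, the last being Timp2 at -0.96.

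No probe set passed limma's test for the mean of hypoxia (0 of 25801, smallest adjusted p = 0.156), and 2011 had an unadjusted p under 0.05. The 10 genes of smallest p, named as not passing, were Srrm2 (-1.35), AU040972 (-1.08), Zfp707 (1.71), Rimklb (at least -1.33), Acta1 (at least -2.80) and Spata5l1 (at least -0.70), each at adjusted p = 0.156, and Ugt8a (at least -1.27, adjusted p = 0.234), Klhdc9 (at least -0.63), Ccdc153 (-0.73) and Timp2 (-0.96, adjusted p = 0.251). Without Norm 1b the cell cycle (median -0.150, adjusted p = 0.862), ciliated (adjusted p = 0.0958) and matrix (median -0.00532) calls ended, and the matrix call also ended without Norm 1a, any 10 h or 2 d sample or 6 d 1b (adjusted p up to 0.863). It ended too with median scaling, the replicate block or the 2 d group left out (adjusted p up to 0.201). The skeletal muscle call could not be tested without Norm 1b. The F test over the 4 comparisons called 319 probe sets, among them the representative probe sets of 137 genes, and 5054 had an unadjusted p under 0.05.

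Between the early and late times in low oxygen, a lysozyme probe set and Ppp1ca rose and Ankrd37 fell. Lyz1, on a probe set shared with near copies, rose by 2.45 ± 0.25 SE (adjusted p = 0.0240), with group means of 12.79 at 10 h, 10.72 at 2 d, 13.48 at 4 d and 14.93 at 6 d, beside 13.06 in Norm. The probe set of its near copy Lyz2 read 0.19 (adjusted p = 0.744). Ppp1ca rose by 1.61 ± 0.12 SE (adjusted p = 0.00439), from 10.69 at 10 h and 12.08 at 2 d to 13.08 at 4 d and 12.91 at 6 d. Ankrd37 fell by 1.67 ± 0.16 SE (adjusted p = 0.0240), with its low values at 4 d. A probe set of Sftpa1, surfactant protein A, rose by 1.12 ± 0.11 SE (adjusted p = 0.0240). It was chosen after its values were seen, and the probe set that represents Sftpa1 read 0.18 (adjusted p = 0.777).

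Alveolar type 2 genes rose from early to late by a median of 0.25 with 25 of 28 higher (adjusted p = 1.23e-12). Examples were Acoxl at 1.41, Egfl6 at 1.39, Etv5 at 1.17 and Abca3, a lipid transporter of surfactant, at 0.62. Macrophage genes rose by a median of 0.10 with 25 of 33 higher (adjusted p = 0.0265), skeletal muscle genes by 0.25 with 15 of 18 higher (adjusted p = 3.8e-05) and cardiac genes by 0.24 with 23 of 32 higher (adjusted p = 2.00e-04). Examples were Acta1 at 1.81 or more, Smpx at 0.97, Mylpf at 0.90 or more and Tnnt2 at 0.59. Cell cycle genes rose by a median of 0.39 with 43 of 53 higher (adjusted p = 5.76e-09, but adjusted p = 0.0550 with an estimated correlation). Examples were Smc2 at 0.86 or more and Rrm2 at 0.78 or more. With the B and C arrays alone the cell cycle median was -0.0553. Among the early samples, those of 2 d had the raised Gapdh ratios given above.

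Immediate early genes fell from early to late by a median of 0.37 with 23 of 26 lower (adjusted p = 1.23e-12). Examples were Fos at -0.95, Maff at -0.89, Atf3 at -0.73 and Egr1 at -0.55. Glucocorticoid-response genes fell by a median of 0.15 with 15 of 23 lower (adjusted p = 4.75e-04). Examples were Cebpd at -1.05, Mt2 at -1.0 and Mt1 at -0.92, and with the B and C arrays alone the median was 0.0408. Targets of hypoxia-inducible factor fell by a median of 0.09 with 26 of 38 lower (adjusted p = 0.0265), Ankrd37 passing and Bhlhe40 at -0.60. Inflammation genes fell by a median of 0.11 with 15 of 23 lower (adjusted p = 8.97e-04, but adjusted p = 0.0549 with an estimated correlation). Examples were Timp1 at -0.88 and Ccl2 at least -0.58. Smooth muscle genes fell by a median of 0.11 with 17 of 27 lower (adjusted p = 0.0465, but adjusted p = 0.465 with an estimated correlation). Examples were Acta2 at -0.80, Cspg4 at -0.72, Cnn1 at -0.70 and Actg2 at -0.61. Adjusted over the list alone, 10 alveolar type 2, 11 immediate early, 7 glucocorticoid, 2 hypoxia-inducible factor, 7 inflammation, 9 smooth muscle, 6 cardiac, 4 skeletal, 1 macrophage and 2 cell cycle members passed. Of the smooth muscle members 3 were higher (Synm 0.40, Notch3 0.35 and Rgs5, at the floor at 10 h, 2 d and 4 d).

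The late minus early comparison set 4 samples against 4, and limma called 4 probe sets (3 higher and 1 lower), with 2851 at an unadjusted p under 0.05. Further genes of small p did not pass: Cebpd, Etv5 and Ntrk2 (-1.20) at adjusted p = 0.0516, then Fst (at least -1.15), Actb (-1.26), Timp2 (0.86) and Hspa1b (-1.20, adjusted p = 0.0847). Of 10 fits leaving out 1 sample, Ppp1ca passed without either Norm sample or 2 d 1a (adjusted p up to 0.127 in the rest), Ankrd37 without either Norm sample (up to 0.237) and Lyz1 without 2 d 1a (up to 0.340). With no trend all 3 lost their calls (adjusted p up to 0.101), and without 2 d and 4 d (0.165, 0.748 and 0.165 for Ppp1ca, Ankrd37 and Lyz1). Without 2 d Ankrd37 and Lyz1 did (up to 0.196), and Lyz1 with no filter (0.0699) or the hypoxia groups alone (0.0512). The other Ppp1ca probe set read -0.22. Within the runs of deposit, fits chosen after seeing the data, 4 d minus 10 h gave Ppp1ca 2.39 (adjusted p = 0.00184), Ankrd37 -3.04 (adjusted p = 0.00199) and Lyz1 0.69 (adjusted p = 0.681). There 6 d minus 2 d gave 0.83 (adjusted p = 0.0967), -0.30 (adjusted p = 0.645) and 4.21 (adjusted p = 0.0147), and Ntrk2 turned to 0.51. Without 2 d and 4 d, Ntrk2, Actb and Timp2 turned to 0.66, 1.46 and -0.34. The cardiac, inflammation and smooth muscle calls ended at 6 d minus 2 d, where glucocorticoid, hypoxia-inducible factor and skeletal muscle lists turned. At 4 d minus 10 h the macrophage (adjusted p = 0.984) and smooth muscle (adjusted p = 0.145) calls ended. The list calls of hypoxia-inducible factor targets (without 10 h 1a, 10 h 1b, 2 d 1a or 4 d 1b, adjusted p up to 0.304), macrophages (without 10 h 1a, 2 d 1b, 4 d 1a or 6 d 1a, adjusted p up to 0.187) and smooth muscle (without any sample but 10 h 1a and 4 d 1a, adjusted p up to 0.394) ended. With median scaling the macrophage call ended (20 of 33 higher, adjusted p = 0.319), without 2 d the macrophage (0.0959) and cardiac (0.187) calls, and with the replicate block the smooth muscle call (0.0514).

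Genes named in advance for this disease model mostly showed no change that passed the tests. Retnla, a secreted protein of the hypoxic mouse lung, changed by -0.22 at 10 h, 0.70 at 2 d (adjusted p = 0.299), -0.86 at 4 d (adjusted p = 0.742) and 0.02 at 6 d. Edn1 read 1.44 at 2 d (adjusted p = 0.0943, other probe set -0.22), 1.16 at 4 d and 1.21 at 6 d (adjusted p = 0.383), and its mean over hypoxia was 1.51 ± 0.33 SE (adjusted p = 0.357). At 2 d the collagens Col1a1 and Col3a1 read 0.99 (adjusted p = 0.191) and 0.47, tenascin C (Tnc) at least 1.28 (adjusted p = 0.267, Norm at the floor), smooth muscle actin (Acta2) 0.98 (adjusted p = 0.0910, other probe set -1.11) and the heme synthesis gene Alas2 0.63. Hif1a read 0.17 and Bmpr2, a receptor mutated in heritable pulmonary hypertension, -0.26 at 2 d. The sign of Retnla at 10 h and 6 d and of Hif1a at 2 d turned with single samples left out. For Epas1 the representative probe set read 0.63 at 2 d (adjusted p = 0.454, -0.17 with quantile normalization) and an A probe set passed at -2.36 (adjusted p = 0.0247), and for Vegfa the probe sets read -0.87, 0.22 and -1.83. Slc2a1, Nos3 and Top2a lay at the floor in Norm, and at 10 h the first 2 read at least 0.32 and 0.53 and Top2a lay at the floor, while Pdk1 read 0.20 and Ptgis, prostacyclin synthase, 0.10.

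Of 162 tests of 27 lists over 6 comparisons, 40 were called (19 higher and 21 lower), and 27 of the 40 held with an estimated correlation. For the cardiac, glucocorticoid, immediate early, clock, erythroid, hypoxia-inducible factor and ciliated lists the estimate lay under the preset 0.01. Their calls met a less strict test there, so holding adds no support for them. For every list the estimate leaves out the spread of Norm, which all comparisons with Norm share. With no filter on dim probe sets 27 were called (4 higher and 23 lower), 16 of them among the 40. Those 16 were cardiac and skeletal muscle at 10 h, 2 d, 6 d, in the mean and from early to late, lymphocytes at 6 d, and alveolar type 2, cell cycle, glucocorticoid, immediate early and inflammation genes from early to late. The other 24 calls ended, and the 4 higher ones with no filter were all from early to late. Some ended calls nearly kept their medians, such as glucocorticoid genes at 10 h (0.35). Others shrank, such as erythroid genes at 2 d (0.15). Taking in the dim probe sets also changed the genes that each list is set against. A kept or ended call there is therefore no measure of the list alone. Uncalled lists, with their smallest adjusted p over the comparisons, were club and airway cells (0.0821 at 2 d, median -0.28), heat shock (0.153), antioxidant genes (0.163), lipid genes (0.262), alveolar type 1 cells (0.375), vascular tone (0.416), mast cells (0.509, where the median of 0.04 and the test had opposite signs), endothelial cells, neutrophils and oxidative metabolism (0.513 each), and fat cells (0.599).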

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

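The tests of 3' bias, of bright genes and of other splits of the samples were set before their results were seen, while reading the share of bright genes by its interval, the shares of probe sets at the other times, the fits within runs of deposit and the final form and reading of the split test were chosen after results had been seen.

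Control probe sets outside the tested ones set the 2 d samples apart: the mean Gapdh 3' to 5' ratio was 4.12 on A, 4.12 on B and 4.06 on C at 2 d, against 1.19, 1.22 and 1.07 in Norm, and these samples had 480 probe sets past the threshold. Other probe sets of the called genes would go either way if 3' bias alone made the calls, by the rule set beforehand, and of 255 genes 178 had their brightest other probe set going the same way. This share of 69.8% (exact 95% interval 63.8 to 75.4) had a lower bound short of the 70% set beforehand, and even odds are no measure here, since probe sets of a gene share the Norm arrays: among the 200 genes of smallest p the share was 58.0% at 10 h, 56.0% at 4 d and 57.5% at 6 d, beside 71.0% at 2 d. In the 255 genes the called probe set, picked for its small p, had a median absolute change of 1.28. The brightest other one changed by a median of 0.182 in the called direction. The brightest 10% of the tested probe sets held 19.6% of the called ones (16.1 to 23.4), far from the majority that a few bright genes would need, yet not clearly under the bound of 20%. For these probe sets 3' bias may have made part of the calls and cannot be told apart from the time in low oxygen, since every 2 d sample carried it; a response of the lung stays open, untested.

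A test of the difference between late and early times singled out Ankrd37 (-1.67), Lyz1 (2.45), Ppp1ca (1.61) and a probe set of Sftpa1 (1.12). Of the 35 splits of the 8 hypoxia samples into 4 and 4, 2 gave at least 4 probe sets, the real split among them. Since 3 of the splits kept both samples of every time together (with 4, 1331 and 1 probe sets), they are too few to measure chance. The highest other split, 10 h and 4 d against 2 d and 6 d, gave 1331, which points to a structure of the samples and follows the runs of deposit. It joins alternate times. A steady change over time would favour the real split, which gave 4, so the counts argue against that as the source. The 2 d samples also had the raised Gapdh ratios. A batch, the integrity of the RNA and effects of single times cannot be told apart there. Within the runs 4 d minus 10 h gave 6 and 6 d minus 2 d gave 16. A first form of the test, which fitted the 4 early and 4 late samples without the means of the time groups, gave 0 for the real split and 558 for that same other split.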

How the results depend on the processing

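Alternatives with the B and C arrays alone, without the 2 d group, without the 2 d and 4 d groups, with the mean of 10 h and 4 d only, and with 4 d minus 10 h or 6 d minus 2 d only were chosen after seeing the data. Of 3592 alternatives of 167 gene results, 3302 stayed on their side of the threshold with the same direction, 131 lost the call, 75 gained one and 84 turned in sign, 0 of these with a call on either side. Of the 167 gene results 15 were calls, and all 131 losses fell on these. The rest did not pass to begin with and mostly stayed by not passing. Of 865 alternatives of 40 list results 715 kept the call, 135 lost it and 15 reversed. Counts outside 1.5 times the ones reported were as follows, and the cause was not tested except where fewer genes or samples by construction are named. Median scaling gave 1 probe set at 10 h and 8 for late minus early (5 higher and 3 lower); it gave 42 list calls (14 higher and 28 lower). A floor at the 20th percentile gave 2 at 10 h and 1 for the mean. A pseudocount gave 3 at 10 h, 4 at 4 d, 3 at 6 d, 1 for the mean, 19 for late minus early and 618 for the F test. No filter gave 73 at 10 h, 61 at 4 d, 63 at 6 d, 94 for the mean and 87 for late minus early, and 27 list calls (4 higher and 23 lower). Requiring 5 arrays above the floor gave 2, 4, 3 and 20 at 10 h, 4 d, 6 d and late minus early, and 672 for the F test. No trend gave 319 at 2 d, 0 for late minus early and 178 for the F test, and robust estimation 1 at 10 h and 10 for late minus early. The correlations of the replicate letters across groups lay between -0.158 and 0.134 over 26 pairs, so the letters do not pair the samples; the replicate block gave 217 at 2 d and 114 for the F test. Adjustment within an array type gave 1 at 10 h, 733 at 2 d and 7 for late minus early. Representative genes alone gave 2 at 10 h, 112 at 2 d, 8 for late minus early and 99 for the F test. Fits to the groups of the contrast, with fewer samples by construction, gave 0 at 2 d, 0 at 4 d and 9 for late minus early, and were not run for the mean or the F test, whose groups are all 5. Without the 2 d group late minus early gave 1 and the F test 0, and without 2 d and 4 d late minus early gave 0. In place of late minus early, 6 d minus 2 d gave 16 (8 higher and 8 lower), with list medians of 0.0564 for glucocorticoid genes, 0.0628 for targets of hypoxia-inducible factor and -1.78e-15 for skeletal muscle. The B and C arrays alone, which hold fewer genes, gave 7 for late minus early and 11 list calls, 8 of them among the 40. With them list medians reversed for skeletal muscle at 10 h (-8.88e-16, from a test now pointing higher), 2 d (0.0682), 6 d (0.00195), the mean (0.178) and late minus early (0.117, with the test pointing lower), cell cycle at 4 d (-0.0138) and late minus early (-0.0553) and glucocorticoid genes at late minus early (0.0408). Without Norm 1b, which takes the A arrays out of comparisons with Norm, they reversed for cell cycle at 4 d (-0.299, the range over samples left out being -0.299 to 0.692) and the mean (-0.150 to 0.399), macrophages at 6 d (-0.252 to 0.253) and matrix for the mean (-0.00532 to 0.218). Too few genes were left for 3 of the 40 list calls with the B and C arrays alone (inflammation at 10 h and late minus early, lymphocytes at 6 d) and for 7 without Norm 1b (glucocorticoid and inflammation at 10 h, lymphocytes at 6 d and skeletal muscle at 10 h, 2 d, 6 d and the mean). An estimated correlation gave 31 list calls, 27 of them among the 40. Leaving out 1 sample gave 0 to 21 at 10 h, 13 to 406 at 2 d, 0 to 20 at 4 d, 0 to 12 at 6 d, 0 to 37 for the mean, 0 to 6 for late minus early, 0 to 496 for the F test and 27 to 52 list calls. Genes that turned in sign were, with quantile normalization, Bmpr2 0.106 at 10 h, Epas1 -0.168, Pdk1 5.89e-05 at 2 d, Retnla -0.0154, Epas1 -0.144 at 6 d, Eln 0.0558, Hba-a1 0.251 late minus early. With median scaling they were Hif1a -0.0663, Alas2 -0.0825 at 4 d, Pdk1 -0.00282 in the mean, Alas2 -0.00463 late minus early. With the replicate block they were Col1a1 -0.0106, Eln -0.0801 at 10 h, Top2a -0.105, Pdk1 0.0445 at 2 d, Vegfa -0.0145, Alas2 -0.118 at 4 d. Without the 2 d group they were Timp2 -0.123, Vegfa -0.392, Col1a1 0.327, Eln 0.896, Hba-a1 0.915, Nos3 -0.0393 late minus early, Acta2 -0.0155 in the mean. Without 2 d and 4 d they were Ntrk2 0.664, Actb 1.46, Timp2 -0.341, Retnla 0.239, Vegfa -0.728, Hif1a 0.00161, Col1a1 0.574, Eln 1.34, Hba-a1 1.18 late minus early. With the mean of 10 h and 4 d only they were Vegfa 0.230, Alas2 -0.125, Hba-a1 -0.154. With 4 d minus 10 h only they were Vegfa -0.0550, Col1a1 0.0796, Eln 0.452, Hba-a1 0.646, Nos3 -0.533. With 6 d minus 2 d only they were Ntrk2 0.508, Epas1 -0.474, Alas2 -0.186. Over samples left out, genes that turned ranged as follows: Retnla -0.665 to 0.231, Hba-a1 -1.07 to 0.118, Eln -0.0227 to 0.0925 at 10 h, Bmpr2 -0.0433 to 0.0734, Vegfa -0.458 to 0.862, Col1a1 -0.231 to 0.765, Col3a1 -0.000428 to 0.971, Alas2 -0.309 to 0.421, Acta2 -0.337 to 0.178, Hba-a1 -0.165 to 0.504 at 4 d, Epas1 -0.145 to 0.463, Retnla -0.427 to 0.469, Hif1a -0.000264 to 0.225 at 6 d, Retnla -0.537 to 0.360, Epas1 -0.431 to 0.177 in the mean, Epas1 -0.258 to 0.276, Hba-a1 -0.321 to 0.273, Nos3 -0.0227 to 0.477, Col1a1 -0.324 to 0.174, Hif1a -0.160 to 0.0648, Alas2 -0.0944 to 0.271, Vegfa -0.160 to 0.50, Pdk1 -0.130 to 0.0159, Eln -0.366 to 0.0307 late minus early, Hif1a -0.0557 to 0.394, Pdk1 -0.0207 to 0.00404, Ptgis -0.207 to 0.165 at 2 d. Signal near the floor limits what dim probe sets can show.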

Other observations

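Tests of exchanged labels, of a match across array types and of the clock genes were chosen after the values were seen, as were the genes of the next paragraph and the reading of saturation by intervals, while the tests of saturated and of red cell and surfactant signal were set before.

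Some vessel and airway genes differed at 2 d although their lists as wholes were not called. Lyve1, a receptor of lymphatic vessels, fell by 1.58 (adjusted p = 0.0203), Clec14a of endothelium fell by 0.98 (adjusted p = 0.0232) and Emcn, endomucin, rose by 0.86 (adjusted p = 0.0490). Cyp2f2, an enzyme of club cells, fell by 2.03 (adjusted p = 0.0298). Of vascular tone genes Bmpr1a fell by 1.0 (adjusted p = 0.0278) and Nos1 rose by 1.52 (adjusted p = 0.0459), and Cited2, a target and inhibitor of hypoxia-inducible factor, fell by 1.72 (adjusted p = 0.0249). Of all 13039 genes 202 passed at 2 d. Among them were 3 of 39 endothelial, 2 of 65 vascular tone, 1 of 23 club and airway and 1 of 38 hypoxia-inducible factor genes. The 2 d samples carried the raised Gapdh ratios given above. At 10 h Sox17, an endothelial factor, read 1.98 and the heat shock genes Hspa1a and Hspa1b read 2.14 and 1.85, none passing over all probe sets.

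Clock genes differed between the 2 d and 10 h samples in the pattern of their phases, with Dbp at least -1.92, Nr1d1 at -1.28, Nr1d2 at -1.91, Per1 at -2.03 and Tef at -0.79 against Arntl at 1.51 and Npas2 at 1.60 (2 d minus 10 h). All 7 of 7 followed the opposite phases of the 2 sets, but they were picked for this from a list of 20 after their values were seen, so the score decides nothing. The 2 A arrays of 4 d differed as well, with Dbp 7.88 and 10.50, Nr1d1 9.45 and 10.99 and Per1 8.72 and 10.0 (1a and 1b). For collection at another time of day, which the labels do not give, the score of 7 cannot tell, and an effect of low oxygen on the clock is untested.

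Among the brightest 1% of probe sets, values at 2 d and 6 d, a run of deposit of their own, exceeded those at 10 h and 4 d by a median of 0.39 on A (71 of 84 higher), 0.14 on B (58 of 86) and 0.13 on C (56 of 89). Saturated signal would also make Norm 1b exceed Norm 1a, by over 0.1 on both B and C. The differences were 0.28 on B (0.226 to 0.348) and 0.20 on C (0.0818 to 0.275), so both met the rule set beforehand. By the intervals, a reading chosen later, the smaller (0.199) reaches under the bound, so saturation is not settled. More red cell and surfactant transcripts would leave other bright probe sets level, and the 232 outside those lists differed by 0.195 (0.141 to 0.264), between the bounds of 0.1 and 0.3 set beforehand, while the 27 inside differed by 0.39. For these bright probe sets both may contribute, and they cannot be told apart with these arrays.

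The A arrays labelled Norm 1b and 4 d 1a correlated across genes better with B and C arrays of the opposite label than with their own. For Norm 1b the difference in correlation was 0.157 on B (0.0689 to 0.241) and 0.116 on C (0.0359 to 0.189), and for 4 d 1a it was 0.0747 (0.00273 to 0.156) and 0.0662 (-0.0136 to 0.149), the last including 0. For the A array of 4 d 1b it lay toward its own label, at -0.0504 on B (-0.13 to 0.0239) and -0.074 on C (-0.151 to -0.00505). A lack of match of any array across array types is argued against, since 10 h, 2 d and 6 d arrays on average matched their own group by 0.212 on B and 0.142 on C (0.0961 to 0.186), though 6 d 1b correlated best with a 2 d array on B (0.146, against 0.103 and 0.0983) and 10 h 1a with Norm 1b (0.188, against 0.145 and 0.156). For the A arrays labelled Norm 1b and 4 d 1a, exchanged labels cannot be told apart from 2 arrays that vary, because 1 of their 4 intervals spans 0. The labels were followed throughout. If they were exchanged, every A comparison with Norm would have a 4 d array as its only reference. The A part of late minus early would then hold a Norm array among the late ones. Directions on A could be wrong in all of these. Most members of several lists were measured on A, with 16 of 18 skeletal muscle, 26 of 32 cardiac, 41 of 53 cell cycle and 19 of 23 glucocorticoid genes.

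The array titled Norm 1a on A but found among the B arrays had a median of 727 and a 99th percentile of 2673, against 6651 to 8131 on the other B arrays. It was not used here. The A array of 4 d 1b stood apart. Its highest Spearman correlation with another A array was 0.913, with that labelled Norm 1b, against 0.954 to 0.966 for the rest.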
